A study of Mus with 12 samples.

How the data were processed

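Gene expression was measured with the nCounter mouse IO360 panel in total RNA from formalin-fixed, paraffin-embedded liver tumours of 12 mice, 3 in each of 4 groups. The panel holds 770 genes and 14 control probes, 8 negative and 6 positive. The groups were control IgG, anti-PDL1, anti-CTLA4 and the combination of both antibodies, taken from the sample titles, and each library was 1 mouse.

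The deposited values are signal, normalized barcode counts that the authors made from the raw counts, with 1 factor per library and with low values replaced by a floor of 20. The software, the normalization method and the authors' test are not given in the sources used here. The factor of each library was recovered from the values: above the floor, at least 99.84% of the genes of every library were whole multiples of 1 step, within 0.0075 normalized counts. The same search recovered all 4 steps of simulated data. The control probes were whole numbers and had not been scaled. A gene was listed at 20 where its count or its scaled value lay below 20: the lowest count above the floor was 20 in each library with a factor above 1 and higher in the others. A gene listed at 20 could therefore hold up to 20 times the factor where the factor was above 1, so that the limit differed between libraries and reached 52.49 normalized counts. Recovered counts per library totalled 439149 to 864464. Counting error and the number of mice both limit the precision of every value, and the files give no further measure of it.

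All 770 panel names were matched to the RefSeq table of the mouse assembly GRCm38.p6, 764 as current symbols and 6 as synonyms. The table served for names alone, and no coordinates are given.

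Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 1 mean per group and a residual spread shared by the 4 groups (8 residual degrees of freedom). A planned filter kept genes at or above 20 in at least 3 libraries; it removed no gene because of the floor. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 770 genes, and the threshold was 0.05. The comparisons were the combination, anti-PDL1 and anti-CTLA4 each against IgG, the combination against each single antibody, and the interaction, which is the departure of the combination from the sum of the log2 changes of the single antibodies. Every adjusted p for a gene comes from this limma model unless another is named.

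A set of 31 gene lists (cell type markers, immune and tumour pathways, housekeeping genes) with 499 entries, of which 386 were measured, was fixed before the data were examined. Each list was tested with limma's fry, which asks whether the members of a list move, on balance, in 1 direction and does not compare the list with other genes. The adjustment was over the 31 lists. The mixed form of fry, which asks whether members move in any direction, is given as a second result. The camera test, with a preset correlation of 0.01 and with an estimated correlation, was an alternative. A list score is the mean log2(value + 1) of the members in 1 mouse. Marker lists describe transcript levels in bulk tumour RNA, not cell numbers.

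The genes named in the text follow a rule also fixed before the data were examined. In each comparison with IgG it takes the 8 highest and the 8 lowest log2 fold changes among genes past the threshold, filled up to 4 per direction with the smallest p-values that did not pass. It adds the 2 members with the smallest p of each list past the threshold, and 16 fixed genes. In the other comparisons it takes 4 per direction. A gene or gene group named outside the rule is marked as chosen after its values were seen.

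Where treated libraries lay at the floor, the fitted fold change is no estimate, so a bound was computed instead: the mean log2 value of the IgG libraries minus that of the treated libraries with each floor value raised to the limit of its library. Folds given as "at least" are these bounds. A log2 fold change printed for any other gene with libraries at the floor is the fitted difference of the listed values, not an estimate of the change.

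Alternatives were another filter, pseudocount, scaling (median, housekeeping genes, quantile), limma without the trend, sample quality weights, a fit with only the groups compared, the replicate number as a block, and each library left out in turn. Added after the data were seen were 4 more: genes strictly above the floor in at least 3 libraries, a common floor at the highest limit, only the 7 libraries whose factor did not exceed the highest factor of an IgG library, and a score of hepatocyte genes as a covariate. A count-based test planned for raw counts was not run, because the values are not counts. The fit was tested on simulated data with the same spread, 770 genes and 200 changed genes in each of 10 runs. It recovered 27.1% of changes of 1 log2 unit, 67.6% of changes of 2 units and 87.3% of changes of 3 units, with 4.2% false calls on average. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the results given below.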

Results

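The series asked how MYC-driven hepatocellular carcinomas of mice respond to immune checkpoint antibodies. Anti-PDL1 blocks PDL1, the product of Cd274 and a ligand of the inhibitory T cell receptor encoded by Pdcd1. Anti-CTLA4 blocks the inhibitory T cell receptor CTLA4. Tumours of 3 mice per group, treated with control IgG, anti-PDL1, anti-CTLA4 or both antibodies, gave 12 libraries of normalized counts for 770 genes.

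Recovered counts totalled 480282 to 864464 per library under IgG, 517366 to 832974 under anti-PDL1, 439149 to 601142 under anti-CTLA4 and 457948 to 813701 under the combination. Negative probes had a mean of 12.67 ± 2.90 counts under IgG (SD, n = 3), against 13.25 ± 1.32 under anti-PDL1, 11.83 ± 1.95 under anti-CTLA4 and 13.29 ± 1.37 under the combination. Genes listed at the floor of 20 numbered 49 to 91 in the IgG libraries, 125 to 151 under anti-PDL1, 113 to 210 under anti-CTLA4 and 84 to 154 under the combination. The normalization factor ran from 0.562 to 1.104 under IgG and up to 2.625 in treated libraries. Of the panel, 519 genes lay above the floor in all 12 libraries and 25 lay at it in all 12, among them Foxp3, Il2ra, H2-K1 and H2-DMb1 (Il2ra, H2-K1 and H2-DMb1 were picked after their values were seen). Correlations across genes between mice of a group, in which genes are not independent replicates, were 0.975 to 0.984 under IgG, 0.937 to 0.988 under the combination, 0.817 to 0.941 under anti-CTLA4 and 0.791 to 0.957 under anti-PDL1.

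**Figure D1:**
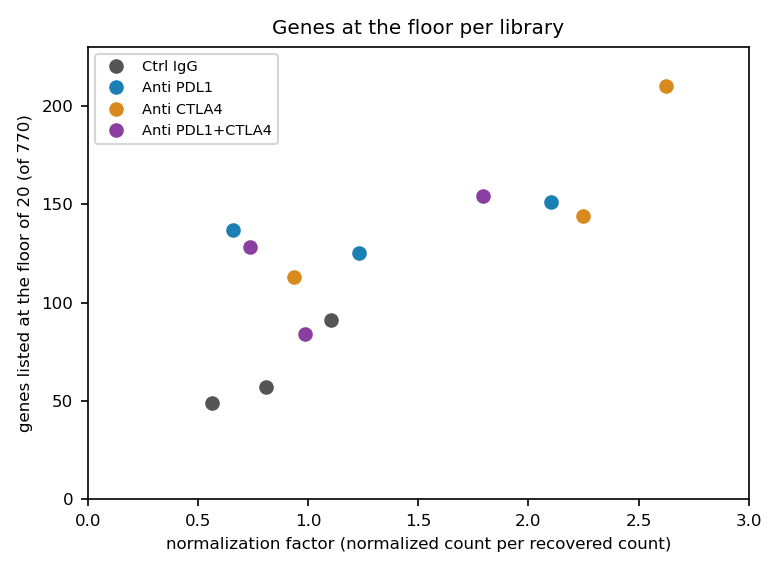
Number of the 770 genes listed at the floor of 20 against the normalization factor of each library (normalized count per recovered count), with 1 point per mouse, coloured by group. The IgG libraries hold 49 to 91 genes at the floor, and the anti-CTLA4 library with the highest factor, 2.625, holds 210.

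Single treated tumours differed in liver and proliferation genes. The liver list (Apoe, Arg1, Fbp1 and 6 other epithelial or liver genes) had a score of 10.66 to 11.10 in the IgG mice, and of 12.64 in Anti CTLA4 2, 12.55 in Anti PDL1 2 and 12.35 in Anti CTLA4 1. Proliferation genes such as Mki67 had scores of 9.13 to 9.23 under IgG, and of 6.34, 7.04 and 8.36 in the same treated tumours. Across the 12 libraries the scores of both lists had a Pearson r of -0.89 (permutation p = 3e-05, two-sided, 100000 permutations) and a Spearman rho of -0.87 (permutation p = 0.00045), the only relation of this kind that was computed. Without the 2 libraries farthest from the median of the liver score, Anti CTLA4 2 and Anti PDL1 2, r was -0.93. The labels give no batch within which it could be computed again. Under the combination, 2 of 3 tumours lay in the IgG range of the liver list, at 10.99 and 11.06, and 1 lay at 11.60.

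The comparison of the combination with IgG asks what blocking both checkpoints does to the tumour transcriptome. Slamf7, a receptor of activated lymphocytes and macrophages, rose from 23.96 ± 6.04 normalized counts under IgG to 76.9 ± 15.5 under the combination (SD, n = 3 each), a fitted log2 fold change of 1.65 (SE 0.324, limma adjusted p = 0.031, higher in 3 of 3 mice than in any IgG mouse). The IgG values lie near the floor, and with a common floor the log2 fold change was 0.52. It was the only gene of 770 to rise in this model, while 21 genes fell to or near the floor. The fallen genes included Dkk1, a secreted Wnt inhibitor, the cytokine genes Ifng, Il6 and Il17a, and Cd8b1, a chain of the CD8 coreceptor. Macrophage, antigen presentation and interferon response genes had higher scores in each of the 3 combination tumours than in each of the 3 IgG tumours, without passing the test in the model that pools the spread of all 4 groups. Such an order of 3 against 3 mice has an exact two-sided p of 0.1. It was not particular to these lists: complement, T cell attracting chemokine, pro-inflammatory macrophage, glycolysis and hypoxia, and endothelial lists had it too. Wnt and regulatory T cell lists had the opposite order.

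Macrophage markers had a score of 8.45 ± 0.21 under the combination and 7.64 ± 0.07 under IgG (SD, n = 3 each). Of the 14 measured, 13 were higher on average, with a median log2 fold change of 0.81 and a fry adjusted p of 0.273. Cd84, a receptor of myeloid cells, had a log2 fold change of 1.07 (SE 0.262, limma adjusted p = 0.0721) and Cd68 of 0.66 (SE 0.422, limma adjusted p = 0.544). None of the 14 passed over all genes, and adjusted over the list alone 1 was higher. Ctss, a protease that prepares peptides for MHC class II, had a log2 fold change of 1.81 (SE 0.468, limma adjusted p = 0.0881), and the inositol kinase gene Itpk1 of 0.66 (SE 0.164, limma adjusted p = 0.0806).

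Presentation genes had similar differences. The MHC class II list scored 8.01 ± 0.26 against 6.66 ± 0.22 under IgG, with a median log2 fold change of 0.75, 7 of 8 members higher, a fry adjusted p of 0.53 and 3 members higher when adjusted over the list alone. H2-Aa and H2-Ab1, which encode the chains of a class II molecule, had log2 fold changes of 2.90 (SE 0.764) and 3.45 (SE 0.914), each with a limma adjusted p of 0.094. They were chosen after their values were seen. The MHC class I list scored 8.49 ± 0.55 against 7.36 ± 0.11 (median log2 fold change 1.18, fry adjusted p = 0.696, 12 of 14 members higher). Adjusted over the list alone, 0 of its members passed.

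Interferon response genes differed in the same direction. Type I interferon response genes scored 8.11 ± 0.15 against 7.21 ± 0.22 under IgG (median log2 fold change 1.00, fry adjusted p = 0.696), with 16 of 18 members higher. Interferon-gamma response genes scored 7.61 ± 0.11 against 6.88 ± 0.01 (median log2 fold change 0.75, fry adjusted p = 0.807), with 14 of 17 members higher. Among them, Cxcl9, a chemokine that draws T cells, was at 234.5 ± 60.6 against 47.3 ± 1.22 normalized counts (log2 fold change 2.26, SE 0.977, limma adjusted p = 0.314). Cd274 was at 181.7 ± 15.5 against 78.1 ± 7.43 (log2 fold change 1.21, SE 0.555, limma adjusted p = 0.341). Pdcd1lg2, which encodes a second ligand of the same receptor, was listed at 32.5 ± 12.2 against 74.0 ± 15.5, with 1 combination library at the floor. Its fitted log2 difference of -1.21 (SE 0.435, limma adjusted p = 0.202) is no estimate and was -0.47 with a common floor. Adjusted over each list alone, 0 members of either interferon list passed.

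These differences depended on which mice set the error. With only the IgG and combination libraries in the fit, an alternative planned before the data were examined, 29 genes were higher and 19 lower, 13 of them shared with the 22 calls from all 4 groups. Cxcl9 then had an SE of 0.221 (limma adjusted p = 0.0122) and Cd274 an SE of 0.158 (limma adjusted p = 0.0191), while their fold changes were unchanged. Over all alternatives the adjusted p ran from 0.00267 to 0.605 for Cxcl9 and from 0.00564 to 0.607 for Cd274. In the same fit the lists of macrophage markers (fry adjusted p = 0.00338), interferon-gamma response (0.00367), type I interferon response (0.0203), MHC class II (0.0203) and complement genes (0.0203) were higher. With an estimated correlation, in the fit of all 4 groups, each of these 5 lists had a camera adjusted p = 0.948. Over all alternatives the adjusted p of these lists ran from 0.00279 to 0.948, from 0.00367 to 0.952, from 0.00958 to 0.948, from 0.0203 to 0.948 and from 0.0183 to 0.948, in the same order. The medians of the macrophage, MHC and interferon lists stayed positive under every scaling tried, although median scaling moved the median of all genes from 0.03 to -0.38. Housekeeping scaling left that median at 0.03 and could change little. The score of the housekeeping list already ran only from 9.09 to 9.17 over the 12 libraries, so that this scaling is hardly a separate check. Among genes above the floor everywhere the unscaled median was 0.28. Subtracting the median of these genes per library, a step chosen after the data were seen, made the score differences smaller. For macrophage, MHC class I, MHC class II, type I interferon and interferon-gamma lists they went from 0.81, 1.12, 1.35, 0.90 and 0.72 to 0.36, 0.67, 0.90, 0.44 and 0.27.

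**Figure D2:**
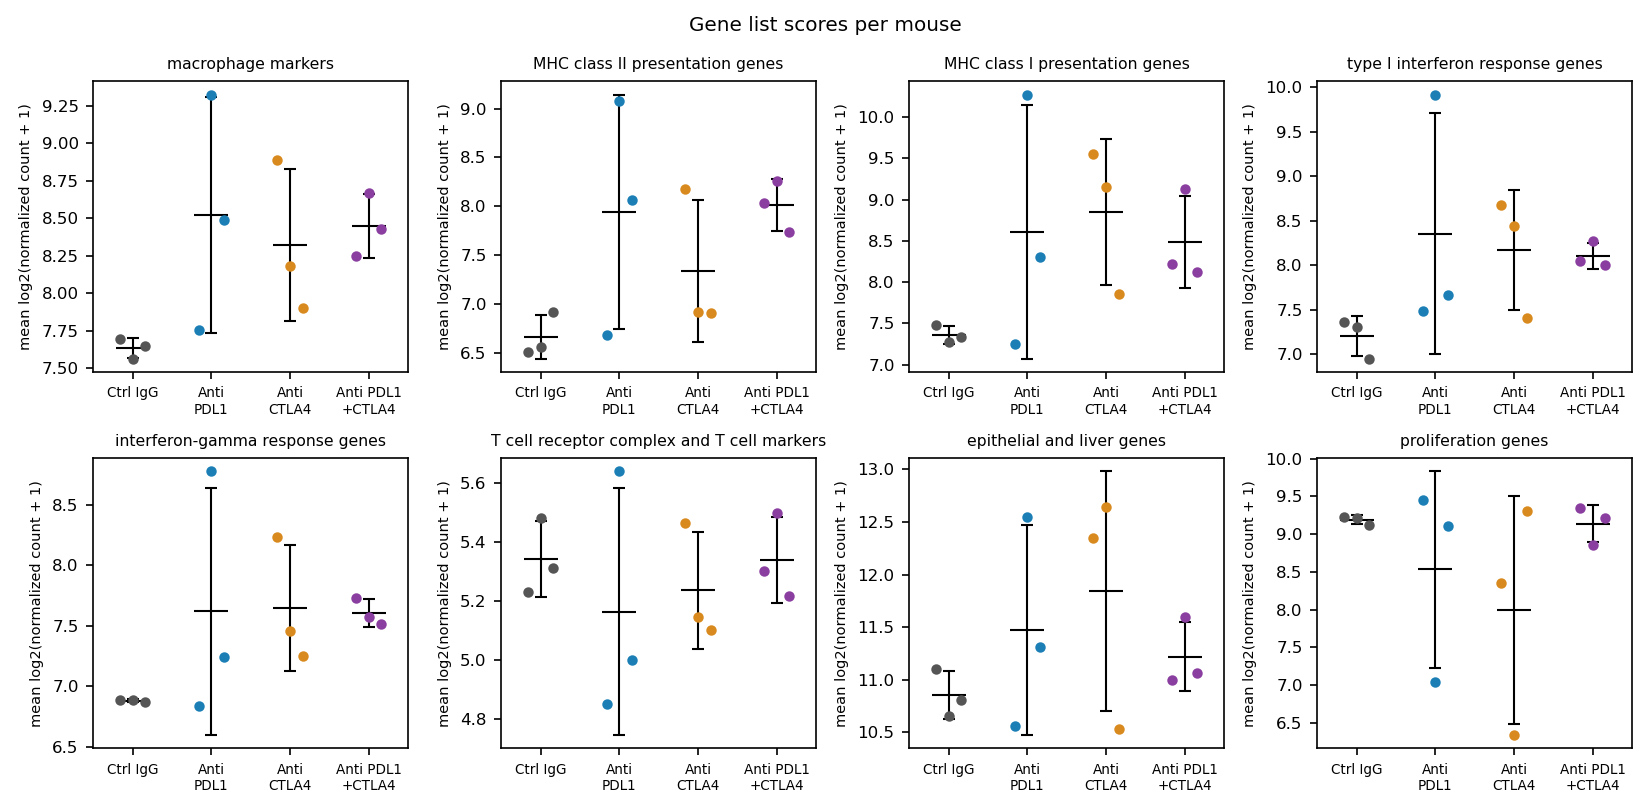
Gene list scores, the mean log2(normalized count + 1) of the members, with 1 point per mouse, the group mean and the SD as bars (n = 3 per group). In the macrophage, MHC and interferon panels all 3 combination mice lie above all 3 IgG mice, and the single-antibody groups spread widely, as in the liver and proliferation panels.

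The 21 genes that fell had IgG means of 28.7 to 59.4 normalized counts. In 14 of them all 3 combination libraries lay at the floor, and in 20 at least 2 did. Dkk1 had 59.4 ± 12.9 normalized counts under IgG and was at least 2.38-fold lower (limma adjusted p = 7.41e-05). Cd70, the ligand of the costimulatory receptor CD27, was at least 2.03-fold lower, Cd8b1 at least 1.97-fold lower, the ciliary gene Ttc30a1 at least 1.96-fold lower and Fam124b at least 1.93-fold lower. Jup, which encodes plakoglobin, was at least 1.67-fold lower, Ceacam3 at least 1.66-fold lower, Il17a at least 1.53-fold lower, Ifng at least 1.49-fold lower and Il6 at least 1.43-fold lower. Adjusted p-values in limma ran from 1.07e-06 for Il6 to 0.0492 for Cd8b1 and Fam124b. Floor values enter the model as exact. Il6 was listed at 20 in all 3 mice of each treated group, which leaves almost no spread. The smallest of these p-values are therefore no measure of certainty. Each of the 3 combination mice lay below each IgG mouse in Dkk1, Cd70 and Cd8b1. In Jup, Il17a, Ifng and Il6 this holds for 2 of the 3, because the limit of Anti PDL1+CTLA4 2, 35.86, lies above the lowest IgG value of these genes. Genes of other tissues went the same way: in libraries of low factor, 13 of 18 genes such as Ren1 and Sox10 were lower in treated mice, with a median log2 difference of -0.38. With the filter at 50, and with a common floor, 0 genes passed.

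B and plasma cell markers were the 1 list of 31 that passed the test of a common direction. Their score was 4.78 ± 0.20 against 5.15 ± 0.27 under IgG, with a median log2 fold change of -0.41 and 7 of 8 members lower (fry adjusted p = 0.0462). The adjusted p was 0.948 with an estimated correlation. Pnoc and Tnfrsf17, which encode a neuropeptide precursor and the plasma cell receptor BCMA, fell from 34.97 ± 3.12 and 28.72 ± 1.45 normalized counts to the floor, at least 1.44-fold and at least 1.18-fold lower. Ms4a1, the B cell antigen CD20 (chosen after its values were seen), was the member that was higher, with a log2 fold change of 0.71 (SE 0.543, limma adjusted p = 0.614). Adjusted over the list alone 4 members were lower, and 4 of the 8 lay at the floor in 9 or more libraries. The call ended without Ctrl IgG 1 and without any 1 of the 3 combination libraries, with 0 lists past the threshold. It also ended with a pseudocount of 10 (adjusted p = 0.0766), housekeeping scaling (0.126), quantile normalization (0.11), only the groups compared (0.072), the replicate number as a block (0.105), the filter at 50 (0.95), genes strictly above the floor (0.314), a common floor (0.786), the hepatocyte score as covariate (0.0563) and without the libraries of high factor (0.13). Over all alternatives the adjusted p ran from 0.00279 to 0.95, with 7 of 22 past the threshold. In fry's mixed test 7 lists passed: pro-inflammatory macrophage genes (adjusted p = 6.65e-07), B and plasma cell markers and Wnt genes (9.55e-06 each), cytotoxic effector genes (5.21e-05), Th1 and activation genes (0.000319), neutrophil genes (0.00463) and alternative macrophage genes (0.0177). Their members called over all genes numbered 1, 2, 3, 1, 2, 1 and 0 in that order. All of these were lower and at or near the floor, so that few members may carry the passes. Camera with an estimated correlation, a test of 1 direction, gave each list an adjusted p of 0.948.

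T cell genes did not pass the test as a group. T cell markers scored 5.34 ± 0.14 under the combination and 5.34 ± 0.13 under IgG (fry adjusted p = 0.946), and cytotoxic effector genes scored 5.38 ± 0.16 and 5.32 ± 0.14 (fry adjusted p = 0.793), with Ifng as the 1 member that fell. Cd8a had a log2 fold change of -0.47 (SE 0.14, limma adjusted p = 0.137), Cd4 of 0.59 (SE 0.313, limma adjusted p = 0.414), Gzmb of 0.03 (SE 0.345) and Prf1 of -0.13 (SE 0.121). Pdcd1 had a log2 fold change of -0.06 (SE 0.361) and Ctla4 of -0.40 (SE 0.287), and Foxp3 was at the floor in every library. NK cell markers scored 4.82 ± 0.05 and 4.81 ± 0.29, regulatory T cell markers 4.66 ± 0.12 and 4.94 ± 0.16 (fry adjusted p = 0.329), and inhibitory receptors 5.18 ± 0.10 and 5.12 ± 0.24. Th1 and activation genes scored 5.32 ± 0.20 and 5.35 ± 0.17 (fry adjusted p = 0.53, with Ifng and Cd40lg fallen), and T cell attracting chemokines scored 6.88 ± 0.05 and 6.49 ± 0.13 (fry adjusted p = 0.946).

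Other lists did not pass either. Wnt and beta-catenin genes had a median log2 fold change of -0.18 (fry adjusted p = 0.141), with 3 of 18 members fallen, Dkk1, Wnt10a and Wnt3a. Proliferation genes scored 9.14 ± 0.25 against 9.19 ± 0.06, with log2 fold changes of 0.63 for Mki67 (SE 1.22) and 0.57 for Myc (SE 0.532). Whether the Myc probe reads the tumours' transgene is not given in the sources used here. The liver list scored 11.22 ± 0.33 against 10.85 ± 0.22, with a log2 fold change of 1.19 for Arg1 (SE 1.14), and complement genes scored 9.03 ± 0.27 against 8.32 ± 0.06 (fry adjusted p = 0.53). Nos2 had a log2 fold change of 0.28 (SE 0.404) and the pro-inflammatory macrophage list a median of 0.28, with a test direction opposite to it (fry adjusted p = 0.946) and Il6 as the 1 member that fell. In 12 of the 31 lists the signs of the median, the mean and the test differed, and the smallest fry adjusted p among them was 0.793. The fry adjusted p was 0.567 for glycolysis and hypoxia genes, 0.807 for collagen and matrix genes and 0.946 for the other lists, which were neutrophil, endothelial, DNA repair, TGF-beta, alternative macrophage, PI3K-MAPK, NF-kB, mast cell, housekeeping, apoptosis and dendritic cell genes. Median scaling, which moved all genes alike, turned the median log2 fold change of proliferation genes from 0.10 to -0.31, that of glycolysis and hypoxia genes from 0.30 to -0.12 and that of T cell markers from 0.02 to -0.39, a common shift that says nothing of these lists in particular.

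In limma, 119 genes had an unadjusted p under 0.05 in this comparison, 55 higher and 64 lower, and the median 95% confidence interval reached 0.91 log2 units to each side. The Slamf7 call ended without Ctrl IgG 1, Ctrl IgG 2, Anti PDL1+CTLA4 1 or Anti PDL1+CTLA4 2 (adjusted p 0.0993, 0.11, 0.14 and 0.124), with the replicate number as a block (0.0625), with the filter at 50 (0.338) and with a common floor (0.41). Its adjusted p ran from 0.0008 to 0.41 over all alternatives. In the reported fit, genes called lower near the floor, Dkk1, Cd70 and Il17a among them, ranked before Slamf7 in the adjustment over all genes. Its limma adjusted p of 0.031 leaned on these lower calls. The count of 22 genes was 12, 14 and 14 without each of the 3 combination libraries in turn. Higher and lower genes numbered 77 and 24 without the libraries of high factor, with 7 calls shared with the 22. They numbered 111 and 79 with sample quality weights, 6 and 14 with quantile normalization, 5 and 33 with median scaling and 16 and 25 with the hepatocyte score as covariate.

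The comparison of anti-PDL1 with IgG asks what blocking PDL1 alone does. Spp1, which encodes osteopontin, rose from 78.9 ± 18.1 to 494 ± 308 normalized counts (SD, n = 3 each; log2 fold change 2.48, SE 0.549, limma adjusted p = 0.0452). Ifngr1, a chain of the interferon-gamma receptor, rose from 145 ± 20.9 to 427 ± 161 (log2 fold change 1.49, SE 0.294, limma adjusted p = 0.0302). Both were higher in 3 of 3 mice than in any IgG mouse. A further 21 genes were called lower, with IgG means of 28.7 to 59.4, and in 18 of them all 3 treated libraries lay at the floor. Sfxn1 and Itpk1 had log2 fold changes of 0.74 (SE 0.172) and 0.70 (SE 0.164), each with a limma adjusted p of 0.0528.

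Of these 21 genes, Dkk1 was at least 2.13-fold lower under anti-PDL1 (limma adjusted p = 6.73e-05), Fam124b at least 1.93-fold, Cd70 at least 1.77-fold, Ttc30a1 at least 1.72-fold and Ccl28, an epithelial chemokine, at least 1.66-fold. Jup was at least 1.48-fold lower, the cadherin gene Cdh11 at least 1.39-fold, Il17a at least 1.36-fold and Ifng at least 1.32-fold. These bounds are averages over the mice. The limit of Anti PDL1 2, 42.02, lies above the IgG means of Jup, Cdh11, Il17a, Ifng, Pnoc and Tnfrsf17. In that mouse no fall of these genes is shown. The genes of other tissues described with the combination were measured over all 3 treated groups, so that their median of -0.38 stands beside these genes too. B and plasma cell markers scored 4.69 ± 0.27 against 5.15 ± 0.27 (median log2 fold change -0.51, 7 of 8 lower, fry adjusted p = 0.0285), and the adjusted p was 0.999 with an estimated correlation. Pnoc and Tnfrsf17 were again the members with the smallest p, at the floor in all 3 mice, at least 1.27-fold and at least 1.05-fold lower. Adjusted over the list alone 4 members were lower.

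Interferon and presentation genes differed between the anti-PDL1 mice. The type I interferon score was 8.36 ± 1.35 against 7.21 ± 0.22 under IgG, with 18 of 18 members higher on average (fry adjusted p = 0.472). The scores were 7.62 ± 1.02 for interferon-gamma response (fry adjusted p = 0.588, Ifngr1 risen), 8.61 ± 1.53 for MHC class I (0.588), 7.94 ± 1.20 for MHC class II (0.472) and 8.52 ± 0.79 for macrophage markers (0.175). Anti PDL1 2 held the highest values, with 712.3 normalized counts of Cxcl9 and 424.4 of Cd274, and Anti PDL1 1 lay at 31.5 and 80.8. Anti PDL1 2 is also the library with a liver score of 12.55, a proliferation score of 7.04 and a factor of 2.10, so that these differences go together in 1 mouse. Cxcl9 had a log2 fold change of 1.27 (SE 0.977, limma adjusted p = 0.517), which turned to -0.04 without Anti PDL1 2, and Cd274 one of 1.06 (SE 0.555, limma adjusted p = 0.351). Regulatory T cell markers scored 4.53 ± 0.03 against 4.94 ± 0.16 (fry adjusted p = 0.102), with 3 members lower when adjusted over the list alone, and a median that turned from -0.30 to 0.01 with quantile normalization. The fry adjusted p was 0.125 for Wnt genes, 0.27 for complement and for Th1 genes, 0.588 for T cell markers and 0.924 or higher for the other 20 lists, liver and proliferation genes among them.

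Among the other fixed genes, Cd8a lay at the floor in all 3 anti-PDL1 mice (limma adjusted p = 0.0528), as did Ctla4 (0.122), Pdcd1 (0.271) and Prf1 (0.248). Log2 fold changes were -1.35 for Pdcd1lg2 (SE 0.435, 1 library at the floor, -0.47 with a common floor), 0.96 for Myc (SE 0.532), 0.29 for Cd4 (SE 0.313), 0.34 for Gzmb (SE 0.345) and 0.36 for Nos2 (SE 0.404). They were 2.15 for Arg1 (SE 1.14), 0.35 for Cd68 (SE 0.422) and 0.30 for Mki67 (SE 1.22). None of these passed. In limma, 146 genes had an unadjusted p under 0.05, 71 higher and 75 lower. Both higher calls ended without any 1 of the IgG libraries, without Anti PDL1 2 and without Anti PDL1 3: the adjusted p then ran from 0.0914 to 0.132 for Spp1 and from 0.0521 to 0.118 for Ifngr1. Both also ended with only the 2 groups compared (0.143 and 0.21, in a fit with 0 higher and 8 lower genes), with the filter at 50 (0.24 each), with a common floor (0.185 each) and without the libraries of high factor (0.098 and 0.115). Spp1 also ended in limma without trend (0.0519) and Ifngr1 with quantile normalization (0.0516). Over all alternatives their adjusted p ran from 0.000118 to 0.24 and from 0.00026 to 0.24. In the reported fit, genes called lower near the floor, Dkk1 and Il17a among them, ranked before Spp1 and Ifngr1 in the adjustment over all genes. The adjusted p-values of Spp1 and Ifngr1 leaned on these lower calls. Higher and lower genes numbered 137 and 145 with sample quality weights, 5 and 10 with quantile normalization, 7 and 26 with median scaling, 15 and 21 with the hepatocyte score as covariate, 5 and 16 with the replicate number as a block and 10 and 17 without Anti PDL1 1. With the libraries of low factor alone 0 genes and 0 lists passed, in a group then left with 1 anti-PDL1 mouse. The count of 23 genes was 14 without Anti PDL1 2 and 15 without Anti PDL1 3, and the list of B and plasma cell markers no longer passed without any 1 of the anti-PDL1 libraries. The list also ended with quantile normalization (adjusted p = 0.0961), only the groups compared (0.22), the replicate number as a block (0.065), the filter at 50 (0.922), genes strictly above the floor (0.189) and a common floor (0.648), and its adjusted p ran from 0.00111 to 0.999 over all alternatives. In fry's mixed test 6 lists passed, each with 1 to 3 members called over all genes, all of them lower.

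**Figure D3:**
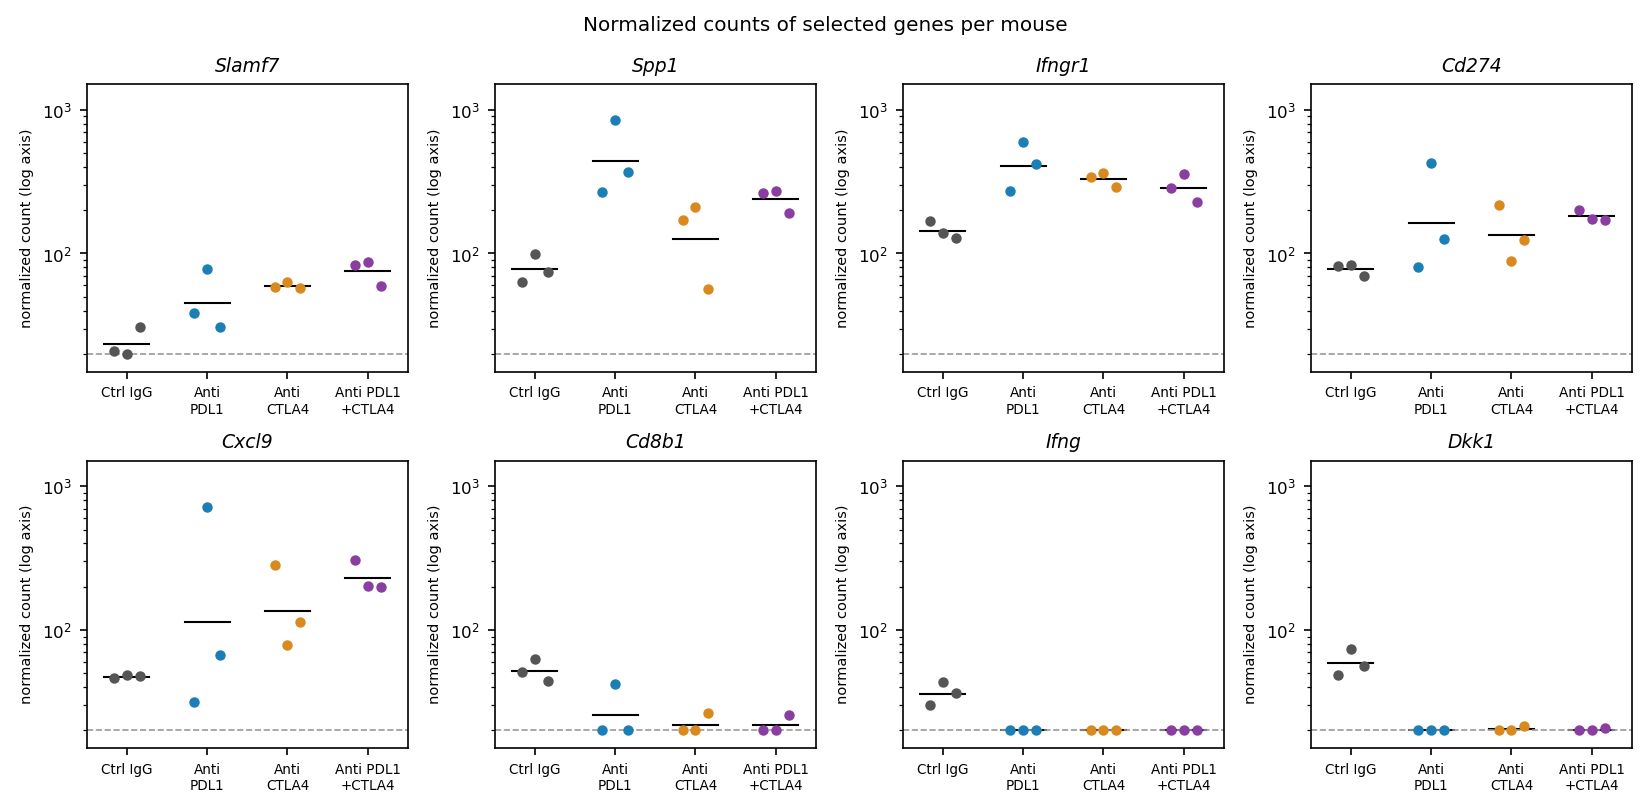
Normalized counts per mouse on a log axis for 8 genes, with 1 point per mouse, the group's geometric mean as a line (n = 3 per group) and the floor of 20 as a dashed line. Slamf7, Spp1, Ifngr1, Cd274 and Cxcl9 have group means above IgG in all 3 treated groups, and Cd8b1, Ifng and Dkk1 lie at or near the floor in most treated mice.

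The comparison of anti-CTLA4 with IgG asks what blocking CTLA4 alone does. No gene rose past the threshold in this model, and 20 genes were called lower, in 17 of which all 3 treated libraries lay at the floor. The count was 32 without Ctrl IgG 3 and 12 without Anti CTLA4 2. Higher and lower genes numbered 4 and 14 with quantile normalization, 3 and 17 with the replicate number as a block, 269 and 92 with sample quality weights, and 6 and 8 without the libraries of high factor, where 0 of the 20 calls were shared and 1 anti-CTLA4 mouse was left. With the hepatocyte score as covariate 0 were higher and 4 lower, 3 of them shared with the 20, and the filter at 50 and a common floor gave 0 genes each. The smallest p-values among higher genes belonged to Dll4, a Notch ligand (log2 fold change 1.03, SE 0.235, limma adjusted p = 0.0537), Ifngr1 (1.19, SE 0.294, limma adjusted p = 0.0706), Slamf7 (1.303, SE 0.324, limma adjusted p = 0.0706, 0.18 with a common floor) and Casp8 (1.54, SE 0.437, limma adjusted p = 0.129). Unadjusted, 165 genes had a p under 0.05, 90 higher and 75 lower.

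Among the genes called lower, Dkk1 was at least 1.58-fold lower under anti-CTLA4 (limma adjusted p = 8.22e-05), Cd70 at least 1.36-fold, Fam124b at least 1.34-fold, Ccl28 at least 1.26-fold and Ceacam3 at least 1.18-fold. Jup was at least 1.12-fold lower, Cdh11 at least 1.06-fold and Il17a at least 1.03-fold. For the other 12 genes, Ifng and Il6 among them, the values of the anti-CTLA4 mice, raised to their limits and averaged in log2, reached or exceeded the IgG mean, so that no fold can be given and no fall is established. The limits were 44.96 and 52.49 in Anti CTLA4 1 and 2 and 20 in Anti CTLA4 3. Those of Anti CTLA4 1 and 2 lie above the IgG means of Ceacam3, Jup, Cdh11 and Il17a. In these 2 mice no fall of these genes is shown, and their bounds above 1 rest on Anti CTLA4 3. Of the 20 genes, 4 lay below IgG by more than the SD of the gene's IgG values. B and plasma cell markers scored 4.96 ± 0.42 against 5.15 ± 0.27 (fry adjusted p = 0.0803), and 0 of 31 lists passed in fry, 4 with an unadjusted p under 0.05 and 9 in its mixed test. The camera test gave 5 lists with the preset correlation and 0 with an estimated one.

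Immune lists again had higher scores that did not pass. They were 8.85 ± 0.89 for MHC class I (fry adjusted p = 0.413), 8.17 ± 0.67 for type I interferon response (0.413), 7.65 ± 0.52 for interferon-gamma response (0.413), 8.33 ± 0.51 for macrophage markers (0.413) and 7.34 ± 0.73 for MHC class II (0.694). Glycolysis and hypoxia genes scored 9.65 ± 0.07 against 9.28 ± 0.05 (fry adjusted p = 0.124), a median log2 fold change of 0.41 that was -0.07 with quantile normalization. Proliferation genes scored 8.0 ± 1.51 against 9.19 ± 0.06 (median log2 fold change -1.17, 18 of 19 lower, fry adjusted p = 0.413), with 8.36, 6.34 and 9.30 in the 3 mice, the last above every IgG mouse, and the liver list 11.84 ± 1.14 against 10.85 ± 0.22 (0.501). For the other lists the adjusted p was 0.141 for regulatory T cell markers and Wnt genes and 0.413 to 0.991 for the rest. Log2 fold changes were 2.68 for Arg1 (SE 1.14), 0.77 for Cd274 (SE 0.555), 1.51 for Cxcl9 (SE 0.977), -1.79 for Mki67 (SE 1.22) and -0.98 for Pdcd1lg2 (SE 0.435, 1 library at the floor, -0.42 with a common floor). They were 0.69 for Myc (SE 0.532), 0.82 for Nos2 (SE 0.404), 0.36 for Cd4 (SE 0.313), -0.25 for Cd68 (SE 0.422), -0.63 for Pdcd1 (SE 0.361), -0.68 for Ctla4 (SE 0.287) and -0.04 for Gzmb (SE 0.345). Cd8a (limma adjusted p = 0.0546) and Prf1 (0.23) lay at the floor in all 3 mice, and none of these genes passed.

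The lower calls of the 3 comparisons with IgG overlapped. Those shared by all 3 numbered 19, with 20 shared by the combination and anti-PDL1 and 19 by the combination and anti-CTLA4. For 12 of the 20 anti-CTLA4 calls no fall is established, as given above. All 3 comparisons use the same IgG mice. Independent lists of the same sizes would share 0.57 calls for the combination and anti-PDL1, 0.55 for the combination and anti-CTLA4 and 0.01 for all 3. Simulated values without any effect, with the shared controls, gave means of 0.01, 0 and 0 over 100 simulations, but hold almost no calls and so give no level for lists of this size. For genes at the floor in all treated libraries, the 3 comparisons set the same IgG values against the same 20. The log2 fold changes of Il17a (-0.866), Jup (-0.989) and Ifng (-0.822) were thus equal in all 3. Overlap of this kind follows from the floor and the shared mice, and is no separate finding in 3 treatments. The IgG mice are too few to be divided between the comparisons.

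The combination was compared with each single antibody to ask what the second antibody adds. No gene passed against anti-PDL1 in limma (smallest adjusted p = 1; 5 with an unadjusted p under 0.05) or against anti-CTLA4 (smallest adjusted p = 0.733; 33 unadjusted). The median confidence interval of these differences reached 0.91 log2 units to each side. With sample quality weights, whose estimation had not converged, 47 genes were higher and 14 lower against anti-PDL1. Against anti-CTLA4 they numbered 56 and 194. Against anti-PDL1, the smallest p-values belonged to Prdm1 (0.72), Itgax (0.86), Ccl3 (0.74) and Tlr1 (0.60) among genes with higher log2 values, and to Hdac4 (-0.80), Twist2 (-1.12), Pdzk1ip1 (-1.02) and Ccl1 (-0.77) among those with lower ones. With a common floor the values were 0.22 for Prdm1, 0 for Ccl3 and -0.27 for Twist2, and Itgax and Ccl1 were left out, so that the fitted values of these genes rest on values near the floor. Against anti-CTLA4, they belonged to the monocyte chemokines Ccl12 (1.27) and Ccl7 (0.86), to Cd7 (1.13) and the macrophage elastase Mmp12 (1.54), and to Egr1 (-1.24), Ihh (-1.35), Wnt2 (-1.07) and Dll4 (-0.69). Mmp12 had a mean of 734.6 normalized counts under the combination and 267.5 under anti-CTLA4 (SE of the log2 difference 0.483, limma adjusted p = 0.733). With a common floor Ccl12 was at 0.24 and Cd7 at 0.07, Ccl7 and Wnt2 were left out, and Mmp12 (1.54), Egr1 (-1.24), Ihh (-1.35) and Dll4 (-0.69) did not move.

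The interaction asks whether the combination departs from the sum of the single changes. In limma, 10 genes passed, all with positive values, led by Fam124b (1.68, SE 0.288, adjusted p = 0.0222), Dkk1 (1.49, SE 0.171, adjusted p = 0.00145), Cd70 (1.14, SE 0.177, adjusted p = 0.0135) and Jup (0.99, SE 0.172, adjusted p = 0.0222). Each of the 10 was listed at or near the floor with either antibody alone, so that a sum of the single changes would lie below the floor, where no value is listed. Ifngr1 (-1.68, SE 0.416, adjusted p = 0.125), Ihh (-2.06, SE 0.627, adjusted p = 0.266), Ifitm2 (-2.06, SE 0.666, adjusted p = 0.321) and Egr1 (-1.57, SE 0.547, adjusted p = 0.345) had the smallest p-values among negative ones. The count was 16, 18 and 24 without Ctrl IgG 1, 2 and 3, 16 without Anti CTLA4 3, 5 without Anti CTLA4 2 or Anti PDL1+CTLA4 3, and 0 with median scaling, the filter at 50, a common floor or the hepatocyte score as a covariate. Positive and negative values numbered 106 and 231 with sample quality weights, 2 and 3 without the libraries of high factor, 14 and 2 without Anti CTLA4 3 and 6 and 1 without Anti PDL1 1.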

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

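The test of the off-tissue genes was fixed before its result was seen. The tests of the negative probes and of the detection limits, the median without 4 of the off-tissue genes and the counts over other splits were chosen after the results they bear on were seen.

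A test of the difference itself singled out 10 genes, in which the combination departed from the sum of the single antibodies. The departures, in log2 units, were 1.68 for Fam124b, 1.49 for Dkk1, 1.14 for Cd70, 0.99 for Jup, 0.87 for Il17a, 0.82 for Ifng, 0.77 for Il6, 0.77 for Pnoc, 0.74 for Tcl1 and 0.50 for Tnfrsf17. All 10 departures were positive, and all 10 genes were listed at or near the floor with either antibody alone. A sum of 2 such falls lies below the lowest value that can be listed, so a positive departure follows from the floor whatever the combination did further. Of 100 splits of the 12 libraries, 6 gave as many genes as the real grouping, and the highest of the others gave 35 against the real 10, so that chance cannot be excluded. Which libraries made up the split with 35 genes is not given here, and the cause of its calls was not tested.

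The genes called lower in the treated groups were Dkk1, Cd70, Ifng and 19 others, 22 over the 3 comparisons with IgG, most of them listed at the floor in treated libraries. Unequal detection limits were tested as the whole cause by raising each floor value to the limit of its library. The median log2 distance from IgG was then still 0.57 (SD over genes 0.27) for the combination and 0.39 (SD 0.27) for anti-PDL1, above 0 in 21 of 21 genes in each. Averaged over the mice, the limits did not reach the IgG means, which argues against limits as the whole cause of these listed differences. The genes were picked as lower in the same mice. In 14 and 18 of them all treated libraries lay at the floor, so that IgG values and limits alone set the distance. It says nothing of why the IgG values were higher. The distance exceeded the SD of the gene's IgG values in 19 and 16 of the 21. For anti-CTLA4 the median was -0.01 and 12 of 20 genes no longer lay below IgG, so that unequal limits stay open there. The distance exceeded the SD of the gene's IgG values in 4 of these 20. Reporter background was tested with the negative probes, which in the 7 libraries of low factor were at 10.02 ± 2.15 normalized counts under IgG and 9.89 ± 1.53 in treated mice. The difference of 0.14 lies far below the 6.64 that would be needed, which argues against a background that the negative probes read.

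A background of another kind stays open. Genes chosen as typical of other tissues (germline, melanocyte, neural, lung, skin, kidney, gut and inner ear genes) had a median log2 difference of -0.38 between the 4 treated and the 3 IgG libraries of low factor, with 13 of 18 lower and 3 higher. The choice does not exclude that tumour cells express some of them. Ihh, Ccl25, Mlana and Magea3 had means of 109, 73.6, 44.3 and 44 normalized counts in these treated libraries too. Ren1 (-2.11), Col17a1 (-1.28), Magea1 (-0.92) and Sox11 (-0.80) had the lowest values, and Mlana (0.37) the highest. Col17a1 is also a member of the matrix list. The classes written beforehand did not name the tissues of Ren1 (kidney), Ccl25 and Ihh (gut) and Otoa (inner ear). Without these 4 the median of the other 14 was -0.44, with 11 lower and 2 higher. If these genes read background and not tumour expression, a higher non-specific signal in the 3 IgG libraries could account for at least part of the fall. The labels name no batch that would separate the IgG libraries from the others. A biological effect shared by all 3 treatments stays open too, untested beyond these values.

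Of the 10 ways to split the 6 libraries of each comparison with IgG, only the real one gave as many genes, which is 1 split in each. The real counts were 22 for the combination, 23 for anti-PDL1 and 20 for anti-CTLA4, and the highest of the other splits gave 1 gene in each. For gene lists the real counts were 1, 1 and 0, the highest of the other splits gave 0, and 1, 1 and 10 splits gave as many. The real count was 0 genes against each single antibody, so that all 10 splits gave as many, and the highest of the others gave 1 against anti-PDL1 and 0 against anti-CTLA4. With 10 splits the share is never under 0.05.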

How the results depend on the processing

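The alternatives chosen after the data were seen were the filter on genes strictly above the floor, the common floor, the fit without the libraries of high factor and the hepatocyte score as covariate. Values are given in the order combination, anti-PDL1 and anti-CTLA4 against IgG, the combination against anti-PDL1 and against anti-CTLA4, and the interaction, unless fewer are named. The reported counts were 22, 23, 20, 0, 0 and 10 genes and 1, 1 and 0 lists. Unless a reason is given, the cause of a change was not tested.

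Without any filter nothing changed, because the floor leaves no gene to remove. With the filter at 50, 606 genes were left and 0 genes and 0 lists passed in limma in any comparison, and the common floor of 52.49 (597 genes) gave 0 as well. Both remove or level the genes near the floor, which ends the lower calls. Spp1 and Ifngr1 under anti-PDL1 kept their log2 fold changes of 2.48 and 1.49 and were lost too (limma adjusted p 0.24 and 0.185 each). The Benjamini-Hochberg adjustment of a gene is milder where more genes have smaller p-values. In the reported fit, genes called lower ranked before Spp1 and Ifngr1, so that these calls leaned on the lower calls. What a changed spread added to the loss was not tested. With strictly above the floor, 724 genes were left and the counts were 18, 19, 16, 0, 0 and 1 genes and 0 lists in each. A pseudocount of 10 gave 19, 21, 16, 0, 0 and 10 genes and 0, 1 and 0 lists.

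Median scaling gave 38, 33, 21, 0, 0 and 0 genes and 6, 6 and 3 lists. Housekeeping scaling gave 25, 27, 25, 0, 0 and 13 genes and 0, 2 and 0 lists, and quantile normalization 20, 15, 18, 0, 0 and 1 genes and 0, 0 and 1 lists. Limma without trend gave 15, 19, 16, 0, 0 and 7 genes and 1, 1 and 0 lists. Sample quality weights gave 190, 282, 361, 61, 250 and 337 genes and 7, 9 and 16 lists. The weights ran from 0.117 for Anti PDL1 2 to 9.874 for Anti PDL1 3, and their estimation stopped before it had converged.

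With only the groups compared, the counts were 48, 8, 10, 0 and 0 genes and 5, 0 and 0 lists, with a spread taken from 6 libraries. With the replicate number as a block they were 14, 21, 20, 0, 0 and 9 genes and 0 lists in each. Equal numbers did not pair the mice consistently. Of 18 pairs of libraries with the same number, 11 had a correlation above 0.1, and the 18 ran from -0.612 to 0.747. Other pairs ran from -0.851 to 0.838, and 6 of 12 libraries correlated best with their own number. Anti-PDL1 and combination libraries of equal number had correlations of 0.694, 0.716 and 0.314. No level without pairing was computed. The camera test gave 5, 6 and 5 lists with the preset correlation and 0 in each with the estimated one.

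Without libraries of high factor, 7 libraries, 700 genes and 3 residual degrees of freedom were left. The counts were 101, 0, 14, 1, 9 and 5 genes and 7, 0 and 0 lists, and each single-antibody group was 1 mouse, assumed to vary like the others. The hepatocyte score as covariate gave 41, 36, 4, 0, 0 and 0 genes and 0, 2 and 0 lists.

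With 1 library left out in turn, the counts ran from 12 to 31, 14 to 32, 12 to 32, 0 to 0, 0 to 1 and 5 to 24 genes, and from 0 to 2, 0 to 2 and 0 to 1 lists. The combination gave 12 genes without its library 1 and 14 without its library 2 or 3. Anti-PDL1 gave 14 without Anti PDL1 2 and 15 without Anti PDL1 3, and anti-CTLA4 gave 32 without Ctrl IgG 3 and 12 without Anti CTLA4 2. The interaction gave 16, 18 and 24 without Ctrl IgG 1, 2 and 3, 16 without Anti CTLA4 3, and 5 without Anti CTLA4 2 or Anti PDL1+CTLA4 3.

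Of 2156 values of the 112 named gene results under these alternatives, 1876 kept their direction and side of the threshold, 173 no longer passed, 69 newly passed and 38 reversed. The reversed values belong to 9 genes, and 0 of them had been called. In log2 units, median scaling, by a shift common to all genes of a comparison, reversed Gzmb (-0.392) and Nos2 (-0.139) in the combination, and Cd4 (-0.064), Gzmb (-0.016) and Mki67 (-0.055) under anti-PDL1. Quantile normalization reversed Pdcd1 (0.248) and Prf1 (0.212) in the combination, Cd68 (-0.021) and Mki67 (-0.061) under anti-PDL1, and Gzmb (0.176) and Prf1 (0.01) under anti-CTLA4. Sample quality weights reversed Pdcd1 (0.455) and Gzmb (-0.024) in the combination and Gzmb (0.399) under anti-CTLA4.

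Without libraries of high factor the reversed values were those of Pdcd1 (0.309) and Gzmb (-0.048) in the combination, Gzmb (-0.119), Cxcl9 (-0.569) and Nos2 (-0.153) under anti-PDL1, and Gzmb (0.037), Cd68 (0.605) and Mki67 (0.298) under anti-CTLA4. With the hepatocyte score as covariate they were those of Pdcd1 (0.104) and Gzmb (-0.041) in the combination, Nos2 (-0.051) under anti-PDL1, and Myc (-0.048) and Cd68 (0.305) under anti-CTLA4. With 1 library left out, Pdcd1 ran from -0.399 to 0.309 and Gzmb from -0.048 to 0.089 in the combination, Mki67 from -0.198 to 1.083 and Cxcl9 from -0.043 to 2.184 under anti-PDL1, and Gzmb from -0.399 to 0.352 and Cd68 from -0.672 to 0.25 under anti-CTLA4. Cxcl9 turned without Anti PDL1 2 and Cd68 without Anti CTLA4 2.

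Background limits the genes near the floor: 25 of 770 lay at it in every library, and the limit reached 52.49 normalized counts in the library of highest factor.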

Other observations

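Every test in this part was chosen after the result it bears on was seen.

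S100a8 and S100a9, which encode subunits of calprotectin, a protein of neutrophils and other myeloid cells, were high in 2 treated tumours. Both genes were chosen after their values were seen. They were at 1559 and 878 normalized counts in Anti CTLA4 3 and at 807 and 267 in Anti PDL1+CTLA4 2, against at most 112 and 36.3 in the IgG mice.

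Macrophage, MHC class I and II, type I interferon and interferon-gamma lists were higher in all 3 combination tumours than in all 3 IgG tumours. The normalization factor was tested as the cause by subtracting the median of the genes above the floor everywhere from each library. The gains were then 0.36 for macrophage markers, 0.67 for MHC class I, 0.90 for MHC class II, 0.44 for type I interferon and 0.27 for interferon-gamma genes, which argues against the factor as the whole cause. The lists were picked as higher in these same mice. Gains above 0 were therefore likely beforehand and say nothing against chance. Non-tumour liver was tested in the 2 combination libraries of low factor, whose liver score differed from IgG by 0.17. The gains there were 0.70, 0.80, 1.22, 0.81 and 0.74 in the same order, so that liver tissue in the libraries is not the whole cause in these 2 mice. An effect of the combination on macrophages and interferon signalling is a hypothesis that may explain the order, found and tested on the same mice. For each single antibody 1 library of low factor was left, Anti PDL1 1 and Anti CTLA4 3, and the question stays open there.

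Taking the 9 antibody-treated mice together against the 3 IgG mice, 0 of 31 lists had an adjusted p under 0.05 in an exact permutation test over 220 splits. The smallest p that 220 splits can give is 0.00455, which for a single list of 31 adjusts to 0.141, so that no list could pass alone. Regulatory T cell markers, with values taken as listed at the floor, lay below every IgG mouse in 9 of 9 (log2 difference -0.34, exact p = 0.00455, adjusted p = 0.141). Of their 6 members, Foxp3 and Il2ra lay at the floor in every library. Genes of other tissues had a median difference of -0.38 in the libraries of low factor, so that lower listed values were not confined to regulatory T cell markers. The sizes are not alike in kind. The -0.34 is a difference of list scores over all 9 treated mice. The -0.38 is a median over single genes in 4 treated libraries, with a common floor. Macrophage markers (0.80, exact p = 0.0182), complement genes (0.87, exact p = 0.0227) and type I interferon response genes (1.00, exact p = 0.05) were above every IgG mouse in 9 of 9, each with an adjusted p of 0.211. MHC class I genes were above in 8 of 9 (1.28, exact p = 0.0455). The median of the genes above the floor everywhere was also above every IgG mouse in 9 of 9. It ran from 7.69 to 8.67 in treated libraries and from 7.57 to 7.63 under IgG, so that part of this order is shared by the panel. Whether any checkpoint antibody shifts these lists is not decided by this test.

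Liver genes were high and proliferation genes low in single treated tumours. The difference of both list scores within a library, in which a factor cancels, was 6.31 in Anti CTLA4 2, 5.50 in Anti PDL1 2, 3.99 in Anti CTLA4 1 and 2.73 in Anti PDL1+CTLA4 2, against 1.44 to 1.87 in the IgG mice. The highest library exceeded the highest IgG library by 4.44, which argues against the factor as the cause. Liver tissue without tumour in the sampled section may be a source, since both list scores had a Pearson r of -0.89 over the 12 libraries. Tumour cells that divide less and keep liver genes would give the same correlation. These cannot be told apart here, since no histology or tumour content comes with the libraries.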
